A study of Mus musculus with 6 samples.

How the data were processed

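RNA from 3 mouse cell populations was hybridised to a pair of Affymetrix mouse expression arrays, here chip A and chip B, which together cover most of the genes known when they were designed. The populations were mature olfactory sensory neurons (OSNs) sorted by green fluorescence from mice in which GFP takes the place of the Omp coding region, the epithelium left after those neurons were removed (here the residual epithelium), and brain from which the olfactory bulbs were excluded. Per the labels, about 500000 sorted cells and about 2500000 residual cells gave the RNA. Each population was measured on 1 array per chip, so there were 6 arrays and no replicates, and whether the RNA on chip B was the same extract as on chip A is not given in the sources used here.

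The deposited values are probe set signals, an intensity on a linear scale with a single colour. Per the submitters' processing notes they were computed with MAS5, which is named for 5 of the 6 arrays and not for brain on chip A, with no version. The mean of the values between percentile 2 and percentile 98 lay between 499.88 and 499.945 on all 6 arrays, the brain array of chip A included, so each array had been scaled to a common level. The background correction, the scaling target and the detection calls are not given in the sources used here. Such scaling fixes the mean of every array, so a population in which a few transcripts take much of the RNA has its other signals lowered, and absolute amounts per cell cannot be compared. For arrays, the number of arrays limits the precision.

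Chip A had 22690 probe sets and chip B had 22575, each with 64 control probe sets that were left out of all gene comparisons. Gene names came from the platform annotation, with 34837 probe sets renamed through their Entrez identifiers to the symbols of the GRCm38.p6 RefSeq table. Of 45137 probe sets, 35041 had a single symbol, 936 had several and 9160 had none. No gene was named from a probe set with several symbols. The files name no genome build, so no coordinates are given.

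Signals below the lower quartile of the 3 arrays of a chip (70.3 on chip A and 79.7 on chip B) were raised to that value, the floor, before log2 ratios were taken within a chip. A gene was counted in a comparison where the higher of its 2 signals reached the chip median (222 on chip A and 243.7 on chip B). Where only the higher signal reached it, the sign of the ratio follows from the filter, and its size does not. Each of the 18193 genes was represented by the probe set with the highest percentile of mean log2 signal on its chip. A ratio whose lower signal was at the floor is given as "at least". Genes were counted as higher or lower from a ratio of 2-fold. With 1 array per population and chip there is no test across samples and no p-value is given. The spread against which ratios were set was taken from probe sets present on both chips and from different probe sets of a gene. It does not stand for the spread between animals.

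The genes named in the text follow a rule fixed before the data were examined. They are the 10 highest and 10 lowest ratios in each OSN comparison and the 5 on each side between residual epithelium and brain, among counted genes whose other counted probe sets had the same sign. Added to these are the 10 genes with the largest smaller-of-2 ratio among those higher in OSNs than in both, the 2 highest and 2 lowest members of each gene list, all counted members of the olfactory transduction list, and Omp, Actb and Gapdh. Gapdh had no probe set with a single symbol. The 28 gene lists were also fixed before the data were examined. For each list of at least 3 counted genes, the median ratio was placed among 10000 random lists of the same size matched on mean log2 signal in 20 bins, as a description of these arrays.

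The computation was tested on simulated arrays with the array noise of the shared probe sets, for the comparison of OSNs with residual epithelium over 11362 counted genes. It called 87 of 88 genes changed 3-fold, 112 of 112 genes changed 8-fold and 0 of 11163 unchanged genes. The gene it did not call was below the signal filter and so not among those counted. The simulated noise had an SD of 0.124 log2 units per array, at which an unchanged gene could hardly reach 2-fold. The 0 calls among unchanged genes follow from that setting and give no rate of false calls for these arrays. Of 100 lists of unchanged genes, 6 lay outside the central 95% of random lists, and a list of raised genes lay at percentile 100. The spread between chips was 0.247 as simulated and 0.284 as recovered. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, and matplotlib 3.10.9 were used.

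Alternatives fixed before the data were examined were floors at percentile 10 and percentile 40, a pseudocount in place of the floor, no signal filter, a filter at percentile 75, ratios centred on their median, quantile normalization, scaling on the probe sets shared by the chips, the median over a gene's probe sets, and leaving out probe sets that can cross-hybridize. Scaling on the hybridization controls, RNAs added in equal amounts to each sample, was added after an offset between the chips was seen.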

Results

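Gene expression was measured in 3 mouse populations to find transcripts enriched in mature olfactory sensory neurons (OSNs), the odour-detecting neurons of the nose. Sorted OSNs, the residual epithelium and brain without olfactory bulbs were each hybridised to 1 array of chip A and 1 array of chip B, so no difference has a replicate check. Median signals ranged from 194.65 to 239.6 on chip A and from 224.7 to 257.7 on chip B.

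Omp, the gene whose promoter drives the sorting marker, had a signal of 11057 in OSNs, 248.8 in residual epithelium and 201.4 in brain (probe set 1422200_at). It was 44.4-fold higher in OSNs than in residual epithelium, and its residual signal was 2.25% of that in OSNs, close to the 1.82% in brain. Omp checks the labels and is not a finding, because cells were sorted by it. GFP takes the place of its coding region in these mice, and whether the probes lie in the replaced part is not known here, so the signal may not be read as intact Omp. A second Omp probe set, 1422199_at, lay below the floor in all 3 populations. Actb, a cytoskeletal actin, had signals of 12555, 14779 and 16436 in the same order, and its other probe set had 1305, 654.3 and 899.1. The Gapdh control probe set on chip A had 11234, 7614 and 11544.

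The spread of a ratio was taken from 99 probe sets present on both chips. For OSNs over residual epithelium, their log2 ratios on the chips correlated across probe sets (r = 0.931) and differed by 0.23 on average with an SD of 0.25. The average difference was -0.19 with an SD of 0.29 for OSNs over brain, and -0.42 with an SD of 0.34 for residual epithelium over brain. Different probe sets of the same gene differed more, with an SD of 0.62, 0.79 and 0.78 in the same order. The actin control had a ratio of 3′ to 5′ signal, a sign of RNA quality, of 1.42 in OSNs, 1.23 in residual epithelium and 1.23 in brain on chip A. The Gapdh control had 0.79, 0.86 and 0.76 in the same order, so the controls did not rank the arrays alike. The SDs between chips may hold more than array error, because it is not given whether both chips had the same RNA extract. Those between probe sets of a gene also hold differences between the probe sets. Neither can stand for the spread between animals.

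**Figure D1:**
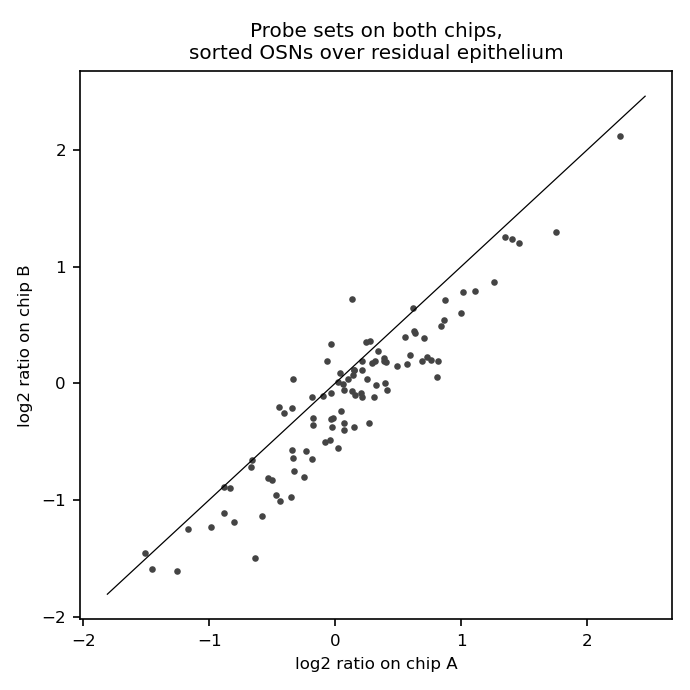
Log2 ratios of sorted OSNs over residual epithelium for the 99 probe sets on both chips, chip A on the horizontal axis and chip B on the vertical axis, with the line of equality. Ratios were on average 0.23 higher on chip A.

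The comparison of OSNs with residual epithelium asks which transcripts belong to the mature neurons within the epithelium. The genes of odour transduction were among the most enriched. Of 17 counted genes of the olfactory transduction list, 13 were at least 2-fold higher in OSNs and 1 was lower, with a median log2 ratio of 3.50, above all 10000 random lists. Cnga4 and Cnga2, subunits of the olfactory cyclic nucleotide-gated channel, were 82.8-fold and 18.0-fold higher. Gnal, the olfactory G protein alpha subunit, was 41.1-fold higher, Adcy3, the adenylyl cyclase it activates, 18.3-fold, and Ric8b, an exchange factor for that G protein, 11.3-fold. S100a5 (44.5-fold), Stoml3 (43.6-fold), Slc17a6 (12.7-fold), Gng13 (11.9-fold), Slc24a4 (10.6-fold), Pde4a (8.23-fold), Pde1c (4.89-fold) and Ncam2 (2.92-fold) were also higher. Slc12a2, Cnrip1 and Dnajc30 were within 2-fold, with log2 ratios of 0.50, -0.28 and -0.86. Rgs2, a regulator of G protein signalling, was 22.5-fold lower in OSNs. Probe sets of some of these genes disagreed in size, from 1.17 to 5.36 log2 units for Gnal and from 0.55 to 5.04 for Pde1c.

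**Figure D2:**
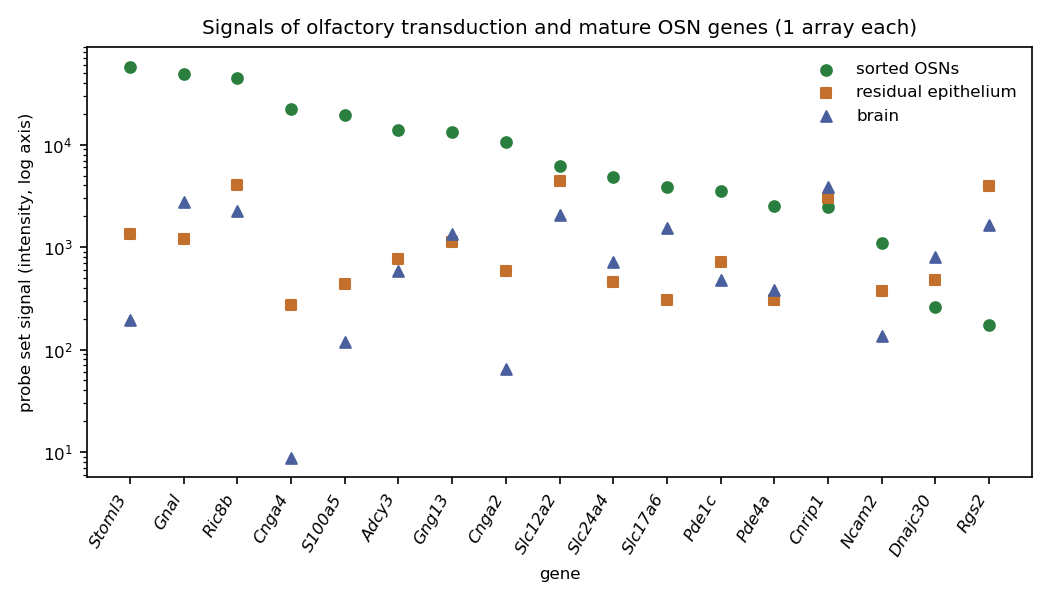
Probe set signals on a log axis for the 17 counted genes of the olfactory transduction list, 1 point per array, in sorted OSNs (circles), residual epithelium (squares) and brain (triangles). Stoml3 reached 57983 in OSNs and 1329 in residual epithelium, while Rgs2 was 174.1 in OSNs and 3914 in residual epithelium.

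Outside that list and apart from Omp, the largest ratio was that of Nrn1l, a relative of the neurite growth protein neuritin (159.7-fold). Next were Togaram2, a microtubule-binding protein (at least 118-fold), the potassium channel gene Kcnc4 (at least 58.7-fold) and Them6 (52.2-fold). Then came Dcdc2a, which encodes a doublecortin-domain protein (47.5-fold), and 1700012B09Rik (43.2-fold). A second Dcdc2a probe set was only 0.44 log2 units higher. Odorant receptors were counted for 26 of the 39 on the arrays, and 23 were at least 2-fold higher and none was lower (median 1.94, above all random lists). Most of those counted passed the signal filter through the OSN array only, which fixes the sign of their ratios. Olfr672 was 17.3-fold higher and Olfr73 at least 12.5-fold, while Olfr315 and Olfr701 had log2 ratios of 0.35 and 0.39. The 3 counted vomeronasal receptors, Vmn2r29, Vmn1r148 and Vmn1r44, stayed within 2-fold (median 0.41, percentile 85.5).

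Cilia genes were higher in OSNs as groups. Among intraflagellar transport and Bardet-Biedl genes, which build and load cilia, 21 of 34 were at least 2-fold higher and none was lower (median 1.15), led by Bbs1 (4.37-fold) and Ttc8 (4.30-fold), with Bbs12 and Ttc21b at 0.05 and -0.91. In the transition zone list 8 of 17 were higher and none was lower (median 0.99), with Tulp3 3.89-fold and Cep290 3.47-fold higher and Mks1 at 0.13. Probe sets of Tulp3 ranged from -0.10 to 1.96 and those of Ttc21b from -0.91 to 0.25. Of 25 motile cilia genes, 23 were higher and 1 was lower (median 2.49). Some of them, such as Armc4, Foxj1 and Hydin, passed the signal filter through the OSN array only, which fixes the sign of their ratios. Rsph4a, a radial spoke protein, was 13.3-fold higher and Enkur 12.5-fold, while Ak7 was at 0.79 and Cfap43 was 2.43-fold lower. Each of these 3 medians lay above all random lists.

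Presynaptic genes were higher in OSNs for 12 of 19 and lower for none (median 1.75), with Snap25 8.44-fold and Syn2 6.77-fold higher, and axon guidance genes for 12 of 21 with 1 lower (median 1.88), with Pcdh10 9.35-fold and Slit1 8.07-fold higher and Sema3a 2.14-fold lower. Both medians lay above all random lists. In the list of immature OSN and neurite growth genes, 9 of 17 were at least 2-fold lower in OSNs and 1 was higher (median -1.15, below all random lists). Cxcr4, a chemokine receptor, was 23.8-fold lower and Nhlh2 9.30-fold lower, and Stmn4 was 6.35-fold higher. All 7 counted progenitor genes were lower (median -2.49, percentile 0.02), among them the transcription factors Neurod1 (29.2-fold) and Neurog1 (at least 16.9-fold). All 26 counted cell cycle genes were lower (median -2.90, below all random lists), with the proliferation marker Mki67 54.1-fold and Ube2c 31.3-fold lower. Only 8 cell cycle genes were counted against brain. Most of the 26 therefore passed the signal filter through the residual array only, which fixes the sign of their ratios. Blood and marrow lists were lower in the same arrays, with medians of -4.85 for neutrophil and marrow genes and -4.08 for both lymphocyte and erythroid genes. Dividing marrow cells also use cell cycle genes, and Cxcr4 and the progenitor list members Kit and Ezh2 are known from blood precursors too, so these lists are not specific to neuronal precursors. OSN transcription factors went both ways, with 4 of 15 higher, 3 lower and a median of 0.28 (percentile 78.8). Rfx4 was 22.3-fold and Ebf4 4.66-fold higher, and Nfia was 4.96-fold lower. Of 5 vomeronasal and guanylyl cyclase D neuron genes 3 were lower and 1 was higher (median -1.81, percentile 0.01), with Pde2a 7.07-fold lower and the G protein gene Gnao1 2.44-fold higher. Probe sets of Nfia ranged from -2.31 to -0.50 and those of Pde2a from -2.82 to -0.17.

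Blood and marrow genes were lower in OSNs. All 12 neutrophil and marrow genes were lower (median -4.85), as were all 20 myeloid genes (median -3.82), all 5 erythroid genes (median -4.08) and 8 of 9 lymphocyte genes (median -4.08). Against brain, only 3 neutrophil and marrow genes, 3 lymphocyte genes and none of the erythroid genes were counted. Most genes of these 3 lists therefore passed the signal filter through the residual array only, which fixes the sign of their ratios. The largest single ratios toward residual epithelium, of genes in these lists or outside them, were those of the antimicrobial peptide gene Camp (at least 124-fold), the secreted protein gene Bpifb9b (104-fold), S100a8 (90.1-fold), the lysozyme gene Lyz1 (85.7-fold), Lcn2 (at least 84.6-fold), S100a9 (77.2-fold), Chil3 (at least 76.0-fold), Srgn (at least 69.5-fold), the red cell anion exchanger Slc4a1 (at least 60.7-fold) and the lymphoid transcription factor Ikzf1 (at least 57.4-fold). Laptm5 was 2.69-fold lower, but its probe sets ranged from -4.73 to 0.56. The erythroid median lay at percentile 0.01 and the other 3 medians below all random lists.

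Lists for other cells of the nasal mucosa had negative medians of smaller size. Markers such as Krt15 and Trp63 were at the floor in OSNs, so their ratios are bounds and the lists cannot be ranked by depletion. Horizontal basal cell genes were lower for 7 of 8 (median -2.08, percentile 7.69), with Krt15 at least 6.41-fold and Trp63 at least 5.59-fold lower. Only 1 gene of this list was counted against brain, so most of the 8 passed the signal filter through the residual array only. Bowman gland and secretory genes were lower for 8 of 10 and higher for 1 (median -1.82, percentile 0.04), with Ltf, which is also in the neutrophil and marrow list, 14.9-fold lower and Cdhr1 3.48-fold higher. Sustentacular cell genes, those of the supporting cells, were lower for 7 of 10 and higher for none (median -1.39, percentile 0.13). Notch2 was 7.60-fold lower, whereas the cytochrome genes Cyp2g1 and Cyp1a2 had log2 ratios of 0.52 and 0.34. Xenobiotic enzymes were split, with 3 of 31 higher and 11 lower (median -0.29, percentile 42.2), from Gsto2 4.94-fold higher to Gsto1 9.54-fold lower. Endothelial and stromal genes were lower for 7 of 9 (median -1.56, percentile 2.20), with Col1a1 6.03-fold lower. Of 2 ensheathing glia genes, Apoe was 16.1-fold lower and Sox10 was at -0.18.

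Among general lists, 15 of 22 dissociation immediate early genes were at least 2-fold lower in OSNs and none was higher (median -2.15, below all random lists), with Socs3 23.0-fold lower. The neutrophil and marrow (-4.85) and myeloid (-3.82) medians were also lower in these arrays. Which cells the immediate early signal came from was not tested. Ribosomal protein genes had a median of -0.84, below all random lists, and 10 of 41 were lower, Rps19 by 4.30-fold. Oxidative phosphorylation genes had a median of 0.45 (percentile 99.8) with 72 of 77 within 2-fold. Brain neuron genes had a median of 0.30 (percentile 76.8) with Camk2a 5.31-fold higher (its probe sets ranged from -0.93 to 2.41), and brain glia genes a median of -0.58 (percentile 2.13) with Cnp 17.9-fold lower and Slc1a2 5.79-fold higher (its probe sets ranged from 0.30 to 2.53).

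**Figure D3:**
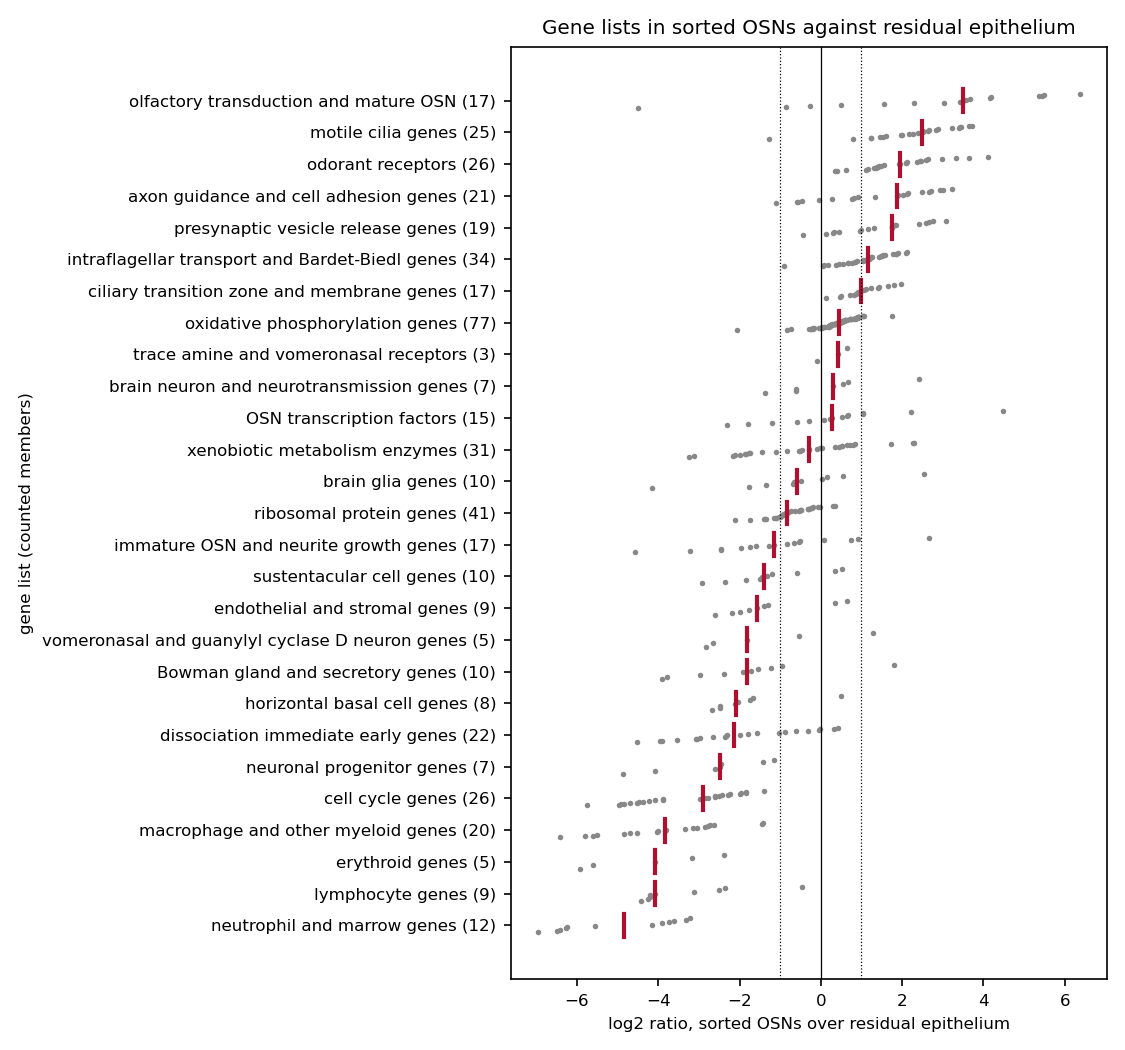
Log2 ratio of sorted OSNs over residual epithelium for the counted members of each gene list (grey points, 1 per gene, height within a row carries no value), with the list median as a red bar and dotted lines at 2-fold. Medians ran from -4.85 for neutrophil and marrow genes to 3.50 for olfactory transduction.

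In all, 1570 of 12254 counted genes were at least 2-fold higher in OSNs than in residual epithelium and 2292 were at least 2-fold lower. A ratio of at least 4-fold was found for 491 and 975 of them. Where a higher gene had other counted probe sets, 93.5% of those had the same sign and 66.5% also reached 2-fold, and for lower genes 92.7% and 65.6% did. The number of lower genes was 1385 with the signal filter at percentile 75, which tests fewer genes.

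Brain without olfactory bulbs served as a source of other neurons and of glia. Against it, 14 of 17 transduction genes were at least 2-fold higher in OSNs and 2 were lower (median 3.02, above all random lists). Gramd1c showed the largest ratio (at least 372-fold), followed by Stoml3 (299-fold), Cnga4 (at least 281-fold), 1700012B09Rik (at least 249-fold), 5730403I07Rik (at least 205-fold), Gm13648 (185-fold), S100a5 (166-fold), the claudin gene Cldn9 (at least 166-fold), Nrn1l (161-fold) and Cnga2 (at least 150.2-fold). Ric8b had a signal of 45258 in OSNs and 2259 in brain. Adcy3 was 23.6-fold and Gnal 17.5-fold higher, and Slc17a6, a glutamate transporter that many brain neurons also use, 2.51-fold. Rgs2 was 9.36-fold and Dnajc30 3.08-fold lower. Probe sets disagreed in size for Gnal (0.66 to 4.13), Dcdc2a (0.57 to 6.09) and Rgs2 (-3.23 to -0.92).

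Odorant receptors were higher than in brain for 25 of 27 and motile cilia genes for 21 of 24 (medians 2.11 and 2.92), with Olfr672 at least 36.7-fold and Enkur at least 109-fold higher. Only 7 odorant receptors and 15 motile cilia genes were counted between residual epithelium and brain. Most of the 27 and some of the 24 therefore passed the signal filter through the OSN array only, which fixes the sign of their ratios. Intraflagellar transport genes were higher for 26 of 34 and transition zone genes for 13 of 17 (medians 1.49 and 1.70), with Traf3ip1 8.41-fold and Rp2 25.8-fold higher. OSN transcription factors, which were mixed within the epithelium, were higher than in brain for 12 of 15 (median 3.43), with Ebf2 67.6-fold and Atf5 31.5-fold higher and Nfia 4.37-fold lower. Axon guidance genes were higher for 13 of 21 and lower for 2 (median 1.33), led by Cntn4 (42.3-fold). Genes of epithelial supporting and gland cells were also above brain in the OSN arrays, 6 of 9 sustentacular genes (median 2.18, with 3 lower) and 7 of 8 Bowman gland genes (median 2.89), among them Cbr2 (38.9-fold) and Bpifa1 (at least 48.8-fold). All of these medians lay above all random lists. The 8 counted cell cycle genes were all within 2-fold of brain (median 0.35, percentile 76.1).

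Genes of brain neurons and glia were lower in OSNs throughout. All 18 counted brain neuron genes and all 14 brain glia genes were at least 2-fold lower (medians -4.79 and -3.71, below all random lists), with the GABA-synthesis gene Gad1 at least 56.3-fold and the myelin gene Mbp 66.6-fold lower. Only 7 brain neuron genes and 10 brain glia genes were counted in OSNs over residual epithelium. Most of the 18 and some of the 14 therefore passed the signal filter through the brain array only, which fixes the sign of their ratios. All 6 counted ensheathing glia genes were lower (median -3.74, percentile 0.02), S100b by at least 43.1-fold, and most of these 6 also passed the filter through brain only. Presynaptic genes were lower for 10 of 19 and higher for none (median -1.07, below all random lists), with Cplx1 9.44-fold lower and Syn2 at 0.52, with Syn2 probe sets from -2.91 to 3.25. The largest ratios toward brain were those of Ttr, the thyroxine carrier made by the choroid plexus (231-fold), Diras2 (at least 185-fold), Frrs1l (at least 127-fold), the splicing factor gene Rbfox1 (at least 117-fold), Sparcl1 (at least 113-fold), Pcp4 (at least 104-fold), Plcxd2 (at least 99.3-fold), the protein kinase gene Prkcb (at least 76.4-fold), Thy1 (72.0-fold) and the calcium buffer gene Calb1 (at least 66.7-fold). Other probe sets gave smaller ratios for some of these genes, with ranges of -6.06 to -0.80 for Calb1, -6.87 to -2.04 for Rbfox1 and -7.61 to -0.42 for Mbp.

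Of 12380 counted genes, 2287 were at least 2-fold higher in OSNs than in brain and 2606 were lower, so 46.7% of calls were higher. With the arrays scaled on the shared probe sets the counts were 1755 and 3223, or 35.3% higher, and the median of all genes moved by -0.28. Where the 2287 higher genes had other counted probe sets, 87.0% of those had the same sign and 53.3% also reached 2-fold. For the 2606 lower genes 93.9% and 77.3% did.

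Residual epithelium was compared with brain as the third pair. The residual arrays were higher for all 26 cell cycle genes (median 3.34), all 12 neutrophil and marrow genes (median 5.17), all 10 Bowman gland genes (median 4.52), 15 of 20 myeloid genes (median 2.71), 7 of 10 sustentacular genes (median 2.68), 11 of 17 immature OSN genes (median 1.46) and 12 of 15 OSN transcription factors (median 2.85), and each of these medians lay above all random lists. Of the cell cycle and the neutrophil and marrow lists, 8 and 3 genes were counted in OSNs over brain. Most of the 26 and 12 therefore passed the signal filter through the residual array only, which fixes the sign of their ratios. The 5 highest single genes were S100a8 (186-fold), the secreted airway protein gene Bpifa1 (at least 184-fold), 5430402E10Rik (at least 179-fold), Bpifb9b (169-fold) and S100a9 (168-fold). Brain was higher for all 18 brain neuron genes (median -4.42) and 17 of 19 presynaptic genes (median -2.77). Most of those 18 passed the signal filter through the brain array only, as in OSNs over brain. The 5 lowest ratios belonged to Hpcal4 (at least 156-fold), Rbfox1 (at least 117-fold), Pcp4 (at least 104-fold), Pcsk1n (at least 85.1-fold) and the sodium channel gene Scn2a (82.5-fold), with Rbfox1 probe sets from -6.87 to -1.55. Of 12916 counted genes 2902 were higher in residual epithelium and 2446 lower, 54.3% of calls being higher, against 2327 and 3119, or 42.7% higher, with scaling on the shared probe sets, which moved the median of all genes by -0.26. The median of the motile cilia list changed sign in this comparison, from 0.55 to -0.06 with that scaling. Where the 2902 higher genes had other counted probe sets, 88.0% of those had the same sign and 56.7% also reached 2-fold. For the 2446 lower genes 93.0% and 76.9% did.

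The series set out to find transcripts enriched in OSNs, so the genes higher than in both other populations were counted. Of 11319 genes counted in both OSN comparisons, 870 were at least 2-fold higher in OSNs than in residual epithelium and than in brain. Ranked by the smaller of the 2 ratios, the first 10 were Nrn1l, Togaram2, Cnga4, Dcdc2a, S100a5, Omp, Stoml3, 1700012B09Rik, Umodl1 and Ctxn3. Umodl1 was 32.7-fold higher than in residual epithelium and 80.1-fold higher than in brain, and Ctxn3 32.0-fold and 51.4-fold. Both comparisons use the same OSN arrays, which raises the overlap by itself. Independent lists of these sizes would share 317 genes, and simulated arrays without any difference, with the spread between probe sets of a gene, shared 294 on average. That simulation used an SD of 0.52 log2 units per array, against 0.124 in the test of the computation. The spread between probe sets also holds differences between the probe sets themselves, so 294 is no baseline for the 870. With 1 OSN array per chip the arrays could not be split, so part of the excess over 317 may come from the shared arrays.

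**Figure D4:**
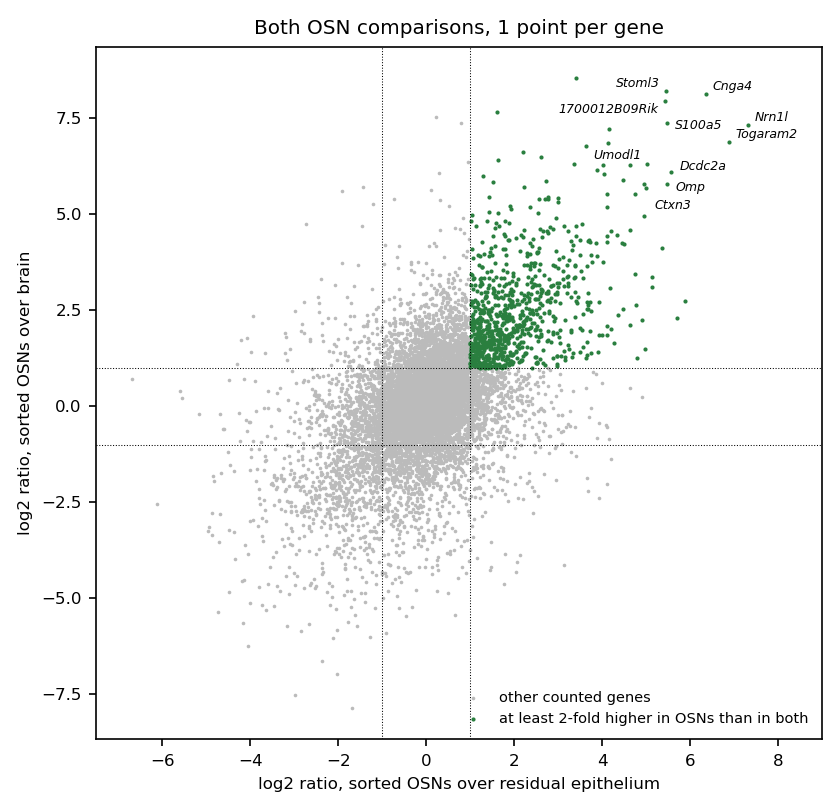
Log2 ratios of sorted OSNs over residual epithelium (horizontal axis) and over brain (vertical axis) for 11319 genes counted in both, 1 point per gene, with dotted lines at 2-fold. The 870 genes at least 2-fold higher in OSNs than in both are green, and the 10 with the largest smaller ratio are named.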

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

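The tests on the whole transduction list and on the span of cell type medians were chosen before their results were seen, and the other tests here were chosen afterwards. The bootstrap intervals were taken by resampling the genes within a list as if they were independent. They hold no spread between arrays or animals.

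Of 9160 probe sets without a gene name, which no comparison used, 3620 passed the signal filter in both OSN comparisons. Of those, 212 (5.86%) were at least 2-fold higher in OSNs than in both other populations, and 44 of them at least 4-fold. For named genes it was 870 of 11319. The highest unnamed probe set by the smaller ratio was 1454386_at, with signals of 4596 in OSNs, 92.1 in residual epithelium and 75.6 in brain. A control probe set for the B1 repeat, outside the gene comparisons, had signals of 3455 in OSNs, 1441 in residual epithelium and 20494 in brain on chip A, and of 12516, 7057 and 54515 on chip B.

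Mature OSN genes kept signal in the residual epithelium, at 1.21% of the OSN signal for Cnga4, 2.29% for Stoml3, 5.57% for Cnga2 and 34.2% for Ncam2, while Slc12a2 (70.6%), Cnrip1 (121%), Dnajc30 (182%) and Rgs2 (2248%) were not enriched. OSNs carried over by the sort would leave the same percentage for all genes of the list. The log2 ratios of the 17 transduction genes had an SD of 2.77 (95% bootstrap interval 1.54 to 3.66), above the bound of 0.93 set at 1.5 times the spread between probe sets. This SD rests in part on those 4 genes, which widen it whatever was carried over. It therefore cannot decide whether carry-over was the only source for the enriched genes. For the 5 members whose brain signal was below the filter the SD was 1.88 (0.41 to 2.50), which includes the bound, so for these genes carry-over and expression by other cells cannot be told apart. Expression in immature neurons stays open as untested.

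Genes of supporting and gland cells kept signal in the OSN arrays. Cells of the residual fraction spread evenly into the sort would give all other cell types the same ratio, if no signal were at the floor. The medians of 9 cell type lists spanned 3.46 log2 units (2.59 to 5.91) against a bound of 1. This cannot decide the question, because the floor limits the ratios of markers such as Krt15 and Trp63. Expression of some members by OSNs would also widen the span. Whether sustentacular cells alone were carried over cannot be decided. The SD within their list was 1.09 (0.56 to 1.38), and this interval includes the bound of 0.93. The members with the highest OSN signals, which do not rank abundance across probe sets, were Cyp2g1 (3822 in OSNs and 2657 in residual epithelium), Cbr2 (2977 and 6857) and Cyp2f2 (2648 and 7244). The sort for GFP would remove such cells unless they stayed attached to neurons, 3 of the 10 genes are also in another list, and which of them OSNs express themselves is not known from these arrays.

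Of 25 motile cilia genes, 23 were at least 2-fold higher in OSNs than in residual epithelium, although olfactory cilia are generally described as immotile in mammals. GFP-negative cells carried over without selection would leave these genes below their residual signal, which the median of 2.49 (1.97 to 2.83) argues against, a value that is the pattern itself and no independent test. Multiciliated cells that entered the sort selectively would bring their genes in a single ratio. The SD over the list was 1.10, and its 95% bootstrap interval began at 0.67, below the bound of 0.93, so selective entry and expression by the OSNs cannot be told apart. The members with the highest OSN signals were Pifo (10571), Enkur (8723) and Cfap206 (6119.5), and the sort for GFP would remove cells without it.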

How the results depend on the processing

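Scaling on the hybridization controls was chosen after the data were seen, and the other alternatives before. No replicate could be left out and no paired analysis was possible because each population has 1 array per chip. Of the 7 counts, 6 stayed within 1.5 times their value under all alternatives run. Genes higher in OSNs than in both ranged from 736 to 933. Genes lower in OSNs than in residual epithelium numbered 1385 with the filter at percentile 75, against 2292, where 7844 genes were counted in place of 12254. Scaling on the hybridization controls moved the split as scaling on the shared probe sets did, to 35.3% of calls higher in OSNs than in brain and 42.9% higher in residual epithelium than in brain, with shifts of the median of all genes of -0.27 and -0.26. The controls had mean log2 signals of 11.88, 11.97 and 11.33 in OSNs, residual epithelium and brain on chip B, and 9.84, 9.75 and 9.86 on chip A. The cause of the offset was not tested. Laptm5 reversed, from -1.43 to 0.56 in OSNs over residual epithelium, without probe sets that can cross-hybridize, because that setting uses another of its probe sets. Of the other alternative values of list medians and named genes, 731 and 3643 moved by less than the SD between the chips and 148 and 631 by more. Most of the alternatives, chiefly the filter at percentile 75 and leaving out probe sets that can cross-hybridize, gave no value for some named genes and short lists, which then had no counted probe set or too few. No list or family median of OSNs over residual epithelium changed sign under a scaling. In the brain comparisons the medians of odorant receptors, vomeronasal receptors and motile cilia genes (residual epithelium over brain), lymphocyte genes and ribosomal genes (OSNs over brain) and xenobiotic enzymes (both) changed sign under at least 1 scaling. Ratios against a signal at the floor are bounds, 99 of the 1570 higher and 473 of the 2292 lower genes in OSNs over residual epithelium.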

Other observations

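The gene families and genes below were chosen after their values were seen, so they describe these arrays only. Of 19 counted genes with a sodium or calcium channel symbol, 10 were at least 2-fold higher in OSNs than in residual epithelium and 1 was lower (median 1.03). This set also holds accessory subunits, Scn4b among them. Signals were 16559.7 and 953.2 for Scn4b, and 9139.6 and 3388 for Scn9a, a sodium channel gene also known from pain-sensing neurons, which had 209.6 in brain. Genes with a potassium channel symbol went both ways, with 17 of 41 higher and 10 lower (median 0.61). The potassium channel set also holds channels not gated by voltage, accessory subunits and the counted opposite-strand transcripts Kcnq1ot1 (-0.51) and Kcnmb4os2 (0.18). Kcna6 had 2394 in OSNs and 21.7 in residual epithelium, while Kcnq3 had 49.7 and 1462. Against brain, 31 of 58 counted genes of the potassium channel set were lower in OSNs, Kcnq1ot1 among them, and 9 higher. Of 27 counted genes of the sodium and calcium channel set, accessory subunits included, 14 were lower and 6 higher.

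Of 6 counted MHC class I genes, B2m included, of 13 on the arrays, 5 were lower in OSNs than in residual epithelium (median -2.45), and 4 of 5 were lower than in brain. H2-D1 had a signal of 223.5 in OSNs, 5829.8 in residual epithelium and 2618 in brain, and B2m had 945, 9281 and 3454. All 4 genes of the inducible proteasome set, the activator subunit gene Psme1 included, were lower than in residual epithelium (median -2.26), whereas all 34 other proteasome subunits were within 2-fold (median -0.10). Against brain, 2 genes of the inducible set were counted, of which 1, Psmb10, was lower in OSNs. The residual arrays also held the blood and marrow genes described above.

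A further 888 genes were at least 2-fold over brain in both epithelial populations and within 2-fold of each other. The highest by the smaller ratio to brain were Gm13648, Cldn9 and Ebf2, with signals of 24892, 13217 and 5919 in OSNs and 21337, 7677 and 4858 in residual epithelium.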
